A study of Mus musculus with 6 samples.

How the data were processed

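Single-cell RNA sequencing was done on mouse tumours grown from Yumm5.2, a cultured mouse melanoma line, implanted under the skin of C57BL/6 mice. Per the labels, all cells carried a short hairpin RNA against Cdkn2a, together with a control hairpin or with 1 of 2 hairpins against Slc39a9, which gives 3 cell lines. Mice received anti-PD1, an antibody that blocks the immune checkpoint receptor PD-1 on T cells, or a control IgG antibody. There were 6 libraries, 1 for each line and treatment, in 4 groups: control with IgG (n = 1), control with anti-PD1 (n = 1), Slc39a9 knockdown with IgG (n = 2, hairpins 1 and 2) and Slc39a9 knockdown with anti-PD1 (n = 2, hairpins 1 and 2). The labels do not say how many tumours went into a library. The replicates of the knockdown groups are therefore different cell lines, and the control has no replicate line.

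Per the labels' protocols, tumours were minced, digested with collagenase and dispase, passed through a strainer and treated with red cell lysis buffer before library preparation with a benchtop single-cell kit. Per the submitters' processing notes, reads were processed with Cell Ranger 7.0.1 against mm10, and the deposited matrix headers name the same version. The deposited values are UMI counts (counts of unique molecular identifiers, so copies made by PCR are counted once) per gene and barcode, not normalised, from matrices already limited to barcodes taken as cells. No deposited cell type annotation was used here. Gene positions come from GENCODE release M21 on the same assembly, in which 30934 of the gene identifiers in the matrices were found.

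The 6 libraries held 43929 barcodes and between 58859821 and 83204249 UMIs each. The lowest UMI count of any barcode was 500 or 501 in each library. Barcodes with fewer than 300 genes or with over 20% mitochondrial UMIs were removed, which left 43843. Scrublet, run in scanpy 1.11.5 for each library with an expected rate of 0.06, marked between 0.866% and 1.66% of barcodes as doublets. They were removed, which left 43260 cells. Cells were normalised, log transformed, reduced to 30 principal components of 2000 variable genes, linked by 15 neighbours and clustered with the Leiden method at resolution 1 without batch correction, which gave 23 clusters (17 at resolution 0.5).

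Clusters were named from marker lists fixed before the data were examined. A name required the highest mean log2 fold change over the other cells, at least 3 markers raised by a log2 fold change of 1, and at least 1 marker among the 10 leading genes of the cluster. No cluster had a melanoma marker among its leading genes together with the melanoma list as its best, so none qualified as melanoma-like. In the cells later taken as tumour-derived, Pax3 was at 55.9 to 81.9 CPM and Mitf at 14.0 to 21.8 CPM, while Tyr stayed at or below 1.51 CPM and Pmel at or below 0.719 CPM. The tumour-derived cells were therefore identified, after the data were seen, by sex-linked genes: 10 clusters expressed Xist and almost no Y-linked genes, while the other clusters, apart from a mixed one, expressed Y-linked genes and little Xist. The labels give the sex of neither the line nor the mice, so taking the first as tumour-derived and the others as host cells is an assumption. The 10 clusters are called tumour-line cells below. Of these clusters 5 (clusters 1, 2, 5, 6 and 10) had a marker of another class among their 10 leading genes and no melanoma marker, and cluster 8 had a low median of 2202 UMIs. For that reason the tumour-line counts were repeated on clusters 0, 3, 4, 8 and 9 alone and without cluster 8, and those for the knockdown, anti-PD1 and single hairpins also in each large cluster by number. Different clusters held the class in different lines: cluster 10 took 23.2% and 23.5% of the cells of the hairpin 1 libraries and between 2.89% and 5.78% of the others, while cluster 0 took between 10.8% and 22.0% of the control and hairpin 2 libraries and 5.35% and 6.97% of the hairpin 1 libraries. The macrophage/monocyte-like class joined clusters 14, 15, 16, 18 and 19. Cluster 19 (90 cells) had 1 marker of its own class and 1 of each of 4 others among its leading genes. Cluster 7 (118 cells) mixed Xist and Y-linked genes and cluster 11 (591 cells) had no name by the fixed markers, and both stayed out of the named classes.

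UMI counts were summed per library and class, and the 6 sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test with default dispersions), with genotype and treatment as terms (3 residual degrees of freedom), with their interaction (2) or with line and treatment (2). P-values were adjusted with the Benjamini-Hochberg method, and a gene with an adjusted p under 0.05 is said to be called. The hairpin 2 minus hairpin 1 contrast was planned. The contrasts of each single hairpin against the control line, in the fit with line and treatment, were added after the data were seen. Log2 fold changes are followed by their standard error. Because labels do not tie libraries to separate animals, p-values measure only the spread between these libraries, and those of the per-line contrasts measure the spread between the treatments of a line. Gene lists, 44 in each class including the marker lists of other cell types, were tested with camera on voom values (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Named genes followed a rule fixed before the data were examined. Among called genes with a mean of at least 20 CPM (counts scaled to a common library total) and 1 direction in every matched difference, the 10 highest and 10 lowest log2 fold changes were taken, without markers of other classes, unnamed gene models and sex-linked genes. For each list called by the set test, up to 4 members with the smallest p were added. Where fewer than 5 genes passed, the 5 highest and lowest with an unadjusted p under 0.05 are given as values. Slc39a9, Cdkn2a, Mt1, Mt2, Slc30a1, Cd274, B2m and H2-K1 were always taken. CPM values use the TMM scaling. Raw CPM values, given for Slc39a9, Cdkn2a and haemoglobin, divide by the UMIs of the class alone.

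Each fit was tested on simulated counts with 200 changed genes drawn from the real means. For the knockdown contrast in tumour-line cells (15653 genes) it recovered 44% of genes changed 1.5-fold and 88% of those changed 2-fold. For anti-PD1 in the same class (15654 genes) it recovered 58% and 88%, and for the interaction (16208 genes) 0% of 2-fold and 36% of 4-fold changes. In macrophage/monocyte-like cells it recovered 96% of 2-fold changes for the knockdown (12123 genes), 94% for anti-PD1 (12154 genes), and 60% of 4-fold changes for the interaction (12533 genes). In the real tumour-line data the knockdown fit called 0 of 15920 genes, not even Slc39a9, whose change was over 2-fold. The recovered shares are therefore not the power of the real fits. Whether the simulated spread matches that between real lines was not tested.

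Both treatments of a line share a cell line, so line pairs the libraries. Deviations from the mean of each treatment, which hold the knockdown difference as well as the line, correlated within the control, hairpin 1 and hairpin 2 lines with 0.867, 0.893 and 0.717 in tumour-line cells and with 0.565, 0.603 and 0.458 in macrophage/monocyte-like cells, and 6 of 6 libraries had their own line as best partner in each class. The fits with line as a block are given where they changed a call or moved a count by over 1.5 times. Libraries of 1 line were not duplicates, since their counts differed by far more than sampling noise.

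Shares of cells were given with exact 95% Clopper-Pearson intervals, and sums of UMIs with exact 95% Poisson intervals. Both cover counting error only. Mean log2 shares were compared with exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3 libraries or 0.067 for 4 against 2. These tests exchange the libraries freely, so they ignore line and do not test differences within lines. The alternatives tried were DESeq2 1.42.0, median-of-ratios size factors, no filter on low counts, doublets kept, a mitochondrial limit of 10%, clusters at resolution 0.5, line as a block and each library left out in turn. Robust dispersions, the 2 other sets of tumour-line clusters, the sums of the libraries of a line (1 residual degree of freedom) and shares without each library were added after the data were seen. The fit with robust dispersions was the first one seen, and the default was then used for all results because the planned design named no robust option. R 4.3.3 and Python 3.11.15 were used. No class other than tumour-line and macrophage/monocyte-like cells had 50 cells in every library, so tests in the others, with at least 20, are alternatives.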

Results

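Single-cell UMI counts were measured in tumours grown from Yumm5.2, a mouse melanoma line, in C57BL/6 mice. The cells carried a hairpin against Cdkn2a, which encodes cell cycle inhibitors, and either a control hairpin or 1 of 2 hairpins against Slc39a9, which encodes a zinc transporter of the ZIP family. For each line 350000 cells were implanted, mice received 200 µg anti-PD1 or IgG 3 times a week, and tumours were taken at 0.5 cm3. The 6 libraries were control IgG (81032820 UMIs), control anti-PD1 (83204249), hairpin 1 IgG (66067282), hairpin 1 anti-PD1 (58859821), hairpin 2 IgG (73356788) and hairpin 2 anti-PD1 (81433435). They held 7601, 8734, 5037, 6095, 7631 and 8162 cells after filtering, in that order. No line and treatment had a replicate library, and the control had 1 line.

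The level of Slc39a9 (ENSMUSG00000048833, protein-coding, mm10 chromosome 12, 80643883 to 80683342, plus strand) shows whether the hairpins lowered their target. In tumour-line cells the control libraries had 22.8 raw CPM with IgG (95% Poisson interval 21.7 to 23.9) and 20.9 with anti-PD1 (19.9 to 22.0). Hairpin 1 had 8.51 with IgG (7.77 to 9.30) and 8.54 with anti-PD1 (7.74 to 9.41). Hairpin 2 had 12.1 with IgG (11.2 to 12.9) and 11.2 with anti-PD1 (10.4 to 12.0). The log2 fold change of knockdown against control was -1.19 ± 0.19 (4 against 2 libraries, lower in 4 of 4 matched differences), with an adjusted p of 0.126 in edgeR and 1.64e-05 in DESeq2. Against the control line, Slc39a9 fell in hairpin 1 (-1.46 ± 0.08, edgeR adjusted p 7.63e-05) and in hairpin 2 (-0.97 ± 0.08, adjusted p 0.00225). Slc39a9 in macrophage/monocyte-like cells, taken to be host cells without a hairpin, was between 23.2 and 25.5 raw CPM, with a log2 fold change of -0.05 ± 0.11. Cdkn2a, targeted in every line, was at 323 and 345 raw CPM in control, 209 and 226 in hairpin 1, and 280 and 325 in hairpin 2 tumour-line cells, IgG before anti-PD1.

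**Figure D1:**
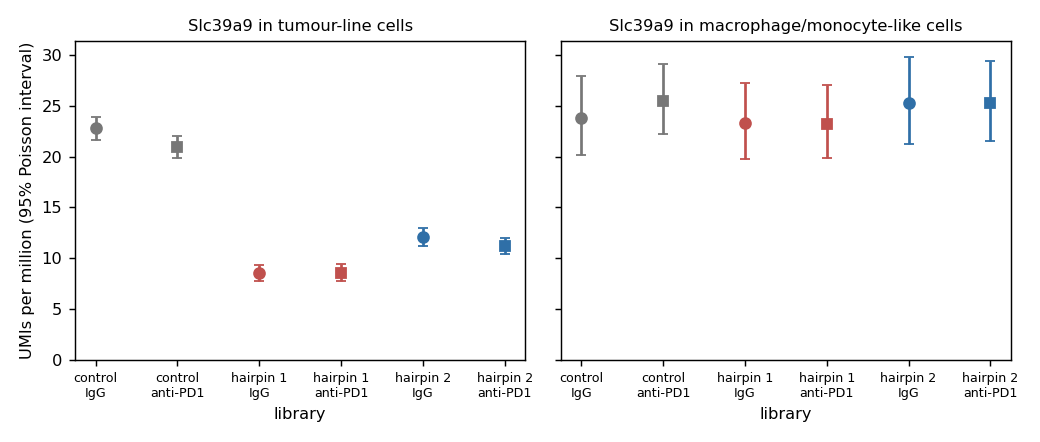
Slc39a9 in tumour-line and macrophage/monocyte-like cells of each library, with 95% Poisson intervals that cover counting error only.

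The knockdown comparison in tumour-line cells asks which genes differ when Slc39a9 is lowered in cells that carry the hairpin against Cdkn2a. No library lacks that hairpin, so its own effect cannot be measured. With both hairpins pooled, the planned edgeR test called 0 of 15920 genes. The single hairpin contrasts given here and in the next paragraphs were chosen after the data were seen. They compare 1 line with 1 line, so their p-values measure the spread between the treatments of a line, not between lines. For single hairpins, rose and fell describe these lines and not a tested effect of the knockdown. Trib3, a pseudokinase gene induced by ATF4, fell against the control line in hairpin 1 (log2 -2.52 ± 0.16, edgeR adjusted p 9.68e-05) and hairpin 2 (-2.43 ± 0.15, adjusted p 0.00133). Asns, which makes asparagine, fell by -0.73 ± 0.05 and -0.88 ± 0.05 in the same contrasts (adjusted p 0.000166 and 0.00133). Within clusters 0, 2, 3 and 4 the pooled Asns log2 fold change was -0.18, -0.50, -0.20 and -0.62. Of 24 tested genes of the amino acid stress (ATF4) list, 18 were called lower and 2 higher in hairpin 1, and 16 lower and 0 higher in hairpin 2. Over all 15920 genes, 3328 were called higher and 3371 lower in hairpin 1, and 1200 higher and 1165 lower in hairpin 2. The list counts here and below are to be read against these. The mitotic kinase gene Cdk1 rose by 0.74 ± 0.09 in hairpin 1 and 0.68 ± 0.09 in hairpin 2 (adjusted p 0.00104 and 0.00725). Of 36 genes of the G2/M list 34 were called higher in hairpin 1 and 22 in hairpin 2, and of 33 S phase genes 29 and 18. Within the 8 large clusters the pooled Cdk1 log2 fold change was 0.06 to 0.65, and cluster 3, led by cell cycle genes, held 5.85% and 6.50% of the control and 9.31% to 11.1% of the knockdown cells.

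Interferon gamma response genes were called higher in both hairpin lines, 16 of 24 with hairpin 1 and 13 with hairpin 2, and 1 was called lower in each. Nlrc5, a regulator of MHC class I genes, rose by 1.77 ± 0.20 and 1.58 ± 0.20. Cxcl9 stayed low in these cells, at 0.0292 and 0.0447 CPM in control and between 0.963 and 2.33 CPM in knockdown libraries, while macrophage/monocyte-like cells of knockdown tumours held 84.4 to 108 CPM. Of 19 genes of MHC class I presentation 14 were called higher in hairpin 1 and 6 in hairpin 2. H2-K1, a class I heavy chain with close paralogs, rose by 2.09 ± 0.10 in hairpin 1 and 0.84 ± 0.09 in hairpin 2. B2m, the class I light chain, rose in hairpin 1 (0.26 ± 0.07, adjusted p 0.0265) and had 0.04 ± 0.07 in hairpin 2 (adjusted p 0.748), with 0.15 ± 0.12 for both pooled. Of 23 type I interferon response genes 5 were called higher and 2 lower in hairpin 1 (median log2 -0.05), and 16 higher and 0 lower in hairpin 2 (median 1.13). Cluster 9, led by Ifit3 and Ifit1, held 0.744% and 0.776% of control, 0.771% and 0.715% of hairpin 1 and 2.94% and 1.10% of hairpin 2 cells, anti-PD1 before IgG. Within clusters 0, 2, 3 and 4 the pooled Ifih1 value was -0.03, 2.00, 0.90 and 0.68. The Xaf1 value was 0.01, 0.33, 0.33 and 0.63, and the Bst2 value 0.43, 0.37, 0.57 and 0.44. Oasl2 had 0.68, 0.76 and 0.86 in clusters 0, 3 and 4.

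Metallothioneins, which bind zinc and are induced by it, fell in both lines: Mt1 by -1.14 ± 0.15 and -0.58 ± 0.15 (adjusted p 0.00154 and 0.0457), Mt2 by -1.46 ± 0.11 and -0.59 ± 0.11 (adjusted p 0.000194 and 0.0184). The zinc exporter gene Slc30a1 fell in hairpin 1 (-1.27 ± 0.14, adjusted p 0.000791) and had -0.48 ± 0.14 in hairpin 2 (adjusted p 0.0573). Of 19 zinc and metallothionein genes 9 were called lower and 0 higher in hairpin 1, and 4 lower and 1 higher in hairpin 2. Of 28 glycolysis and hypoxia genes 13 were called lower and 2 higher in hairpin 1, and 18 lower and 1 higher in hairpin 2, among them the oxidoreductase gene Ero1l (-1.03 ± 0.13 and -0.89 ± 0.13). Within single clusters the pooled Ero1l value ran from -0.84 to 0.27 and was positive in 4 of 8, and cluster 4, which Ero1l helps to mark, held 11.4% and 14.0% of the control and 5.04% to 7.39% of the knockdown cells. The mix of tumour-line clusters was not tested as a source of the knockdown differences. Of 26 antioxidant (NRF2) genes 13 were called lower in each line, and 3 and 0 higher, with Nqo1 at -0.78 ± 0.09 and -0.66 ± 0.08 and Hmox1, the haem oxygenase gene, at -1.30 ± 0.16 and -1.81 ± 0.16. Within clusters 0, 2, 3 and 4 the pooled Nqo1 value was -0.13, 0.07, -0.58 and -1.26. The pooled Hmox1 value there was -1.05, -0.48, -0.77 and -0.66. Markers of neutrophils moved with these groups: 10 of 16 were called lower in hairpin 1 and 8 in hairpin 2.

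With both hairpins pooled against control, edgeR called 0 of 15920 genes (3148 at an unadjusted p under 0.05), DESeq2 called 1404 (727 higher, 677 lower), edgeR without the filter on low counts called 57, and edgeR with the libraries of each line summed called 0 (679 at an unadjusted p under 0.05). Run with the hairpin 1 libraries against all others, the same edgeR test called 2854 genes. With the hairpin 2 libraries against all others it called 0. A line apart from the others can therefore give calls where the knockdown grouping gives 0. Adjusted over the list alone, the pooled test called 12 of 24 amino acid stress genes lower, 33 of 36 G2/M and 22 of 33 S phase genes higher, 11 of 24 interferon gamma genes higher and 1 lower, 3 of 19 MHC class I genes higher, 4 of 23 type I interferon genes higher, 13 of 28 glycolysis and hypoxia genes lower, 10 of 26 antioxidant genes lower, 8 of 16 neutrophil markers lower and 0 of 19 zinc genes. Camera with the preset correlation called 20 of 44 lists. With an estimated correlation none of the 20 was called: the adjusted p was 0.349 for amino acid stress, 0.498 for the antioxidant list and neutrophil markers, and 0.543 for the others named here. Fry, which does not compare a list with other genes, called 4 of 44 lists, amino acid stress (adjusted p 0.00936), and antioxidant, invasive dedifferentiated melanoma and neutrophil marker genes (0.0369 each). Among genes with a mean of at least 20 CPM, those named as highest in the pooled test were Nrep (2.58 ± 0.98), Capn6 (2.08 ± 0.50), Osr2 (1.78 ± 0.34), Edil3 (1.60 ± 0.48) and H2-K1 (1.59 ± 0.51), and those named as lowest Lcn2 (-2.69 ± 0.72), Nppb (-1.86 ± 0.43), Abcb1a (-1.80 ± 0.26), Slpi (-1.78 ± 0.36) and Angptl4 (-1.63 ± 0.52), none of them called. Within the large clusters the pooled Abcb1a value ran from -1.97 in cluster 5 to 0.27 in cluster 10. Nppb ran from -1.73 to -0.39 and Nrep from 0.47 to 2.52. Lcn2, where tested, ran from -2.90 to -0.10. Cluster 5, which Nppb and Abcb1a help to mark, held 6.72% and 6.41% of the control and at most 3.39% of the knockdown cells. The mix of clusters was not tested as a source of these values. In single clusters the pooled test called 39 genes in cluster 5, 1 in cluster 6 and 0 in clusters 0, 2, 3, 4, 8 and 10, where edgeR had between 813 and 1728 genes at an unadjusted p under 0.05.

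The contrasts of single hairpins, chosen after the data were seen, called 6699 genes in hairpin 1 (3328 higher, 3371 lower; DESeq2 5239) and 2365 in hairpin 2 (1200 higher, 1165 lower; DESeq2 2089). Both hairpins shared 751 genes higher and 870 lower, and 98 were called in opposite directions. The log2 fold changes of the 2 contrasts correlated with 0.523 and had a covariance of 0.188, where simulated counts without a common change gave 0.476 and 0.0339 from the shared control libraries alone. The simulated lines did not differ from each other, unlike the real ones. A larger real covariance was therefore to be foreseen and does not show a common effect of the knockdown. Both contrasts use the same 2 control libraries, which cannot be split, so a difference of the control line from both others is not separated from an effect of the knockdown. In clusters 0, 3, 4, 8 and 9 alone the counts were 5616 and 1713. Single large clusters gave 282 (cluster 2) to 2943 (cluster 3) genes for hairpin 1. For hairpin 2 they gave 48 (cluster 8) to 631 (cluster 0).

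The hairpin lines were also compared with each other, which measures how far lines with the same target differ. In tumour-line cells 4794 of 15920 genes differed (2489 higher and 2305 lower in hairpin 2). Slc39a9 itself was higher in hairpin 2 by 0.48 ± 0.08 (edgeR adjusted p 0.00614), Mt2 by 0.87 ± 0.11 and Lcn2 by 2.04 ± 0.28, and H2-K1 was lower by -1.25 ± 0.09. The count was 2528 without hairpin 1 anti-PD1, 2928 without hairpin 2 anti-PD1 and 3075 without hairpin 2 IgG. In macrophage/monocyte-like cells 1636 of 12323 genes differed (796 higher, 840 lower), and DESeq2 called 665.

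The knockdown comparison in macrophage/monocyte-like cells asks how host cells differ in tumours with lowered Slc39a9. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine for T cells, rose by a log2 fold change of 2.63 ± 0.15 (edgeR adjusted p 0.00484), from 17.5 and 14.0 CPM in control libraries to between 84.4 and 108 in knockdown libraries. Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), the haemoglobin scavenger receptor, fell by -2.35 ± 0.16 (adjusted p 0.00531), from 162 and 153 CPM to between 25.3 and 36.8. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600), a chemokine for neutrophils, fell by -2.54 ± 0.17 (adjusted p 0.00531). The receptor gene Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705), used in the uptake of dying cells, rose by 1.27 ± 0.13 (adjusted p 0.0221). Slc39a9 did not differ detectably in these cells.

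Of 12323 genes 50 were called, 16 higher and 34 lower. That test takes the 6 libraries as independent, although libraries of a line resemble each other and the control has 1 line. Run with the hairpin 1 libraries against all others, the same test called 499 genes. With the hairpin 2 libraries against all others it called 0. A line apart from the others can therefore give more calls than the knockdown grouping. With the libraries of each line summed, 2 knockdown lines against 1 control line, edgeR called 0 of 13721 genes (638 at an unadjusted p under 0.05). That fit has 1 control sample and 1 residual degree of freedom, so losing calls was to be foreseen, and spread between control lines cannot be measured. In it the 50 genes kept 92.1% to 103% of their log2 fold change (median 99.3%). Other genes that rose were Ccnd2 (1.53 ± 0.19), Mgl2 (1.48 ± 0.14), Iigp1 (1.10 ± 0.10), Cadm1 (1.06 ± 0.14), Gbp2 (32.5 and 41.0 CPM in control, 56.6 to 88.9 in knockdown), Hpgd (21.7 and 21.6 CPM, 41.4 to 54.0), H2-Q7 (0.94 ± 0.12), Tmem176b (0.91 ± 0.13), Rpl10-ps3 (0.80 ± 0.11, annotated as protein-coding under a pseudogene symbol, so its reads are uncertain) and H2-DMa (0.77 ± 0.10). Others that fell were Slpi (-2.04 ± 0.29), Ppbp (-1.99 ± 0.26), Mmp8 (-1.83 ± 0.17), Ccl6 (-1.30 ± 0.16), Slc7a11 (-1.25 ± 0.17), Spic (-1.12 ± 0.15), Cblb (-1.12 ± 0.11), Gpnmb (-1.09 ± 0.13), Plin2 (-0.84 ± 0.11) and Nfkbia (-0.69 ± 0.10). Mgl2, which rose, is on the fixed marker list of dendritic cells, and RNA from dendritic cells was not tested as its source. Markers of neutrophils fell in the same sums: 4 of 15 were called, S100a9 (-3.34 ± 0.35), S100a8 (-3.63 ± 0.48), Cxcr2 (-3.92 ± 0.49) and Mmp9 (-2.35 ± 0.32). Within clusters 14, 15, 16 and 18 Cd163 had log2 fold changes of -2.35, -2.17, -2.96 and -2.66, and Cxcl9 0.67, 2.55, 3.12 and 2.77.

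**Figure D2:**
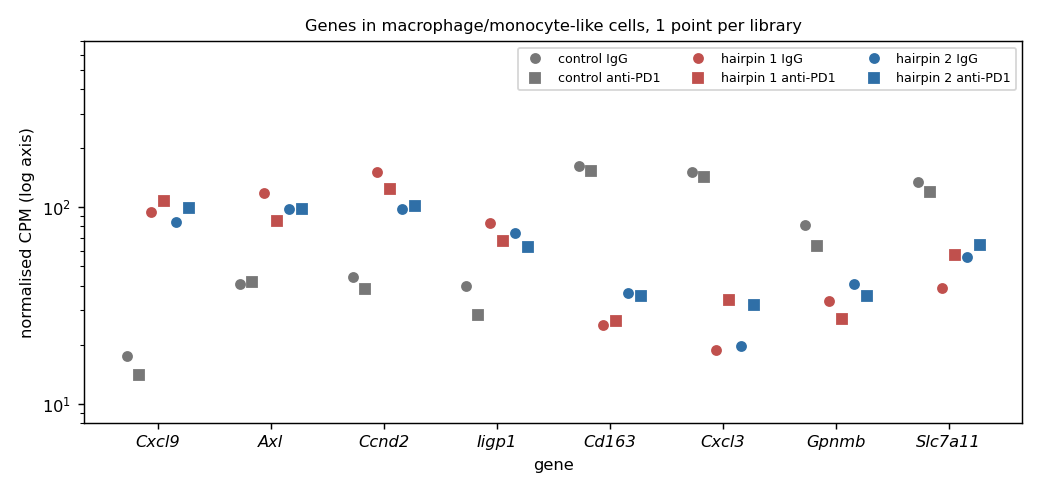
Genes called for the knockdown in macrophage/monocyte-like cells, as normalised CPM in each library.

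Of 22 interferon gamma genes 3 were called higher over all genes and 6 adjusted over the list alone (adjusted p = 0.397 with an estimated correlation). Of 20 MHC class I genes 1 was called higher, and 6 adjusted over the list alone (adjusted p = 0.397), and of 13 MHC class II genes 1 and 7 (adjusted p = 0.452). Of 20 proinflammatory genes 1 was called lower, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.345), and of 22 genes of alternative activation 3 were called lower, and 8 lower and 1 higher over the list alone (adjusted p = 0.345). Of 21 lipid and lysosome genes 2 were called lower and 6 over the list alone (adjusted p = 0.397). Of 33 S phase genes 24 were higher over the list alone (adjusted p = 0.437) and of 36 G2/M genes 0 (adjusted p = 0.482), with 0 called over all genes in either list. Neutrophil markers were lower in 9 of 15 over the list alone (adjusted p = 0.345). Camera with the preset correlation called 21 of 44 lists, and 0 with an estimated correlation. Of the type I interferon list 18 genes were called lower in hairpin 1 (median log2 -0.79) and 10 higher in hairpin 2 (median 0.33). Of the glycolysis and hypoxia genes 3 were called higher and 1 lower in hairpin 1, and 19 lower in hairpin 2.

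DESeq2 called 202 genes (73 higher, 129 lower), and edgeR without the filter on low counts called 969. Without control anti-PD1 the count was 1 and without control IgG 2, and without hairpin 1 anti-PD1, hairpin 1 IgG, hairpin 2 anti-PD1 or hairpin 2 IgG it was 18, 13, 30 and 31. The single hairpins called 2095 genes (1020 higher, 1075 lower; DESeq2 800) and 1133 (477 higher, 656 lower; DESeq2 392), of which 221 were shared higher, 333 shared lower and 70 opposite. Their log2 fold changes correlated with 0.53 and had a covariance of 0.11, where simulated counts without a common change gave 0.48 and 0.0267. Here too the simulated lines did not differ from each other, so this does not show a common effect of the knockdown.

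The anti-PD1 comparison asks what the antibody changes. In tumour-line cells edgeR called 0 genes (135 at an unadjusted p under 0.05) and DESeq2 0. That fit has no line term, so differences between lines enter its spread, and 0 calls do not show that nothing changed. The edgeR fit with line as a block had 986 genes at an unadjusted p under 0.05. With line as a block edgeR called 1 gene, Slpi, a secreted protease inhibitor (log2 0.98 ± 0.06, adjusted p 0.0152), at 108 CPM with anti-PD1 and 60.1 with IgG in control, 23.04 and 10.6 in hairpin 1, and 44.3 and 21.9 in hairpin 2. The other named values were Hspa1b 0.52 ± 0.19, Tinagl1 0.47 ± 0.19, Vdr 0.39 ± 0.12 and Igfbp7 0.34 ± 0.11, and Atp6v0d2 -0.69 ± 0.25, Mgp -0.33 ± 0.12, Arhgef28 -0.29 ± 0.10, Tom1l1 -0.25 ± 0.09 and Mfap3l -0.25 ± 0.08. Camera called 15 of 44 lists with the preset correlation and 0 with an estimated one. Type I interferon genes had a median log2 fold change of 0.36 (21 of 23 positive, 0 called over the list alone, adjusted p = 0.510 with an estimated correlation) and proinflammatory genes 0.31 (18 of 21 positive, 0 called, adjusted p = 0.400). Heat shock and dissociation genes had a median of 0.13 (22 of 23 positive), macrophage markers 0.20 (24 of 29) and neutrophil markers 0.32 (13 of 16), each with 0 called and an adjusted p of 0.400 with an estimated correlation.

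For anti-PD1 in macrophage/monocyte-like cells edgeR called 0 genes (218 at an unadjusted p under 0.05), DESeq2 0, and edgeR without the filter on low counts 17. The edgeR fit with line as a block had 903 genes at an unadjusted p under 0.05. With line as a block 8 were called: the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, whose close paralogs share reads, Retnla (5.05 ± 0.60, with 0 CPM in the IgG libraries of both hairpins), Slfn4 (0.82 ± 0.13), Fn1 (0.47 ± 0.08) and Lncpint (-0.39 ± 0.07). In control anti-PD1 1 barcode held 1768 of 1903 haemoglobin UMIs, and the log2 difference of summed haemoglobin was 4.64, 2.34 and 0.64 in the control, hairpin 1 and hairpin 2 lines with all barcodes and 0.88, 2.55 and 0.76 without the richest barcode of each library. The named values without a call were Slpi 0.77 ± 0.29, Hspa1b 0.70 ± 0.18, Gbp2 0.41 ± 0.11, Rgs3 0.40 ± 0.14 and Cebpb 0.36 ± 0.13, and March3 -0.41 ± 0.09, Akap11 -0.39 ± 0.11, Mecr -0.38 ± 0.15 and Mcph1 -0.37 ± 0.12. Of 44 lists 10 were called with the preset correlation and 0 with an estimated one, among them MHC class I (median 0.09, 20 of 20 positive, 0 called over the list alone, adjusted p = 0.869), MHC class II (median -0.17, 10 of 13 negative, 0 called, adjusted p = 0.869) and haemoglobin (median 3.56 with that barcode included, 4 of 4 called over the list alone, adjusted p = 0.856).

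The interaction asks whether the anti-PD1 difference depends on the knockdown. In tumour-line cells edgeR called 0 of 16564 genes (43 at an unadjusted p under 0.05), DESeq2 0, and the fit with line as a block 1, the neuropeptide gene Gal (-3.42 ± 0.23, adjusted p 0.000975), named after its value was seen. Gal was at 20.96 CPM with anti-PD1 and 13.4 with IgG in control, 0.0199 and 0.0684 in hairpin 1, and 3.99 and 27.6 in hairpin 2. The named values were Mmp13 1.10 ± 0.21 and Itga1 0.54 ± 0.16. In macrophage/monocyte-like cells edgeR called 0 of 12752 genes (76 at an unadjusted p under 0.05), DESeq2 0, edgeR without the filter on low counts 9, and the fit with line as a block 10 (7 higher, 3 lower), among them Hspb1 (3.12 ± 0.58), Saa3 (1.99 ± 0.19), Ppbp (1.26 ± 0.14) and Chil3 (1.20 ± 0.15) higher and Negr1 (-4.42 ± 0.83), Areg (-1.95 ± 0.35) and Hbb-bs (-2.89 ± 0.45, among the haemoglobin genes above) lower. The named values were Ppbp 1.26 ± 0.29, Cmss1 0.87 ± 0.22, Cxcl3 0.85 ± 0.18, Trp53inp1 0.82 ± 0.25 and Mmp8 0.76 ± 0.24, and Epb41l4aos -0.84 ± 0.31, Prps2 -0.83 ± 0.29, Hivep3 -0.72 ± 0.26, Hvcn1 -0.68 ± 0.21 and Lrrc41 -0.66 ± 0.26. The block leaves 1 residual degree of freedom here.

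Shares of cell classes show which cells each tumour yielded. Neutrophils made up 4.96% of cells in control IgG and 5.84% in control anti-PD1, 0.774% and 1.44% in hairpin 1, and 1.42% and 1.98% in hairpin 2. The mean log2 difference of knockdown against control was -2.02 ± 0.48 (SD, n = 4, lower in 4 of 4), with an exact permutation p of 0.0667, the smallest that 4 against 2 libraries allow. The permutation takes libraries of a line as separate units, although line pairs them and the control has 1 line. Neutrophils had a median of 929.5 UMIs, near the lowest count of 500 in the matrices, so their shares depend on that limit. Fibroblasts had a difference of -1.13 ± 0.39 (lower in 4 of 4, exact permutation p 0.0667) and mast cells and basophils 1.10 ± 0.86 (higher in 4 of 4, exact permutation p 0.0667), with 8 to 33 cells per library and values from 0.39 without control IgG to 1.82 without control anti-PD1. For T cells the difference was 0.56 ± 0.82 (exact permutation p 0.333), and -0.0026 without control IgG and 1.13 without control anti-PD1. With anti-PD1, neutrophils had 0.54 ± 0.33 (SD, n = 3, higher in 3 of 3, exact permutation p 0.5), macrophage/monocyte-like cells 0.14 ± 0.10 (exact permutation p 0.2) and tumour-line cells -0.09 ± 0.07 (exact permutation p 0.3). In these tests the differences between lines count as spread, so the p-values do not test the differences within lines. With immune cells alone as the denominator the macrophage/monocyte-like difference was 0.0039. By that denominator neutrophils were 15.90% with anti-PD1 and 15.93% with IgG in control, 4.08% and 2.47% in hairpin 1, and 6.64% and 4.75% in hairpin 2. The control line was therefore not higher with anti-PD1 there.

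**Figure D3:**
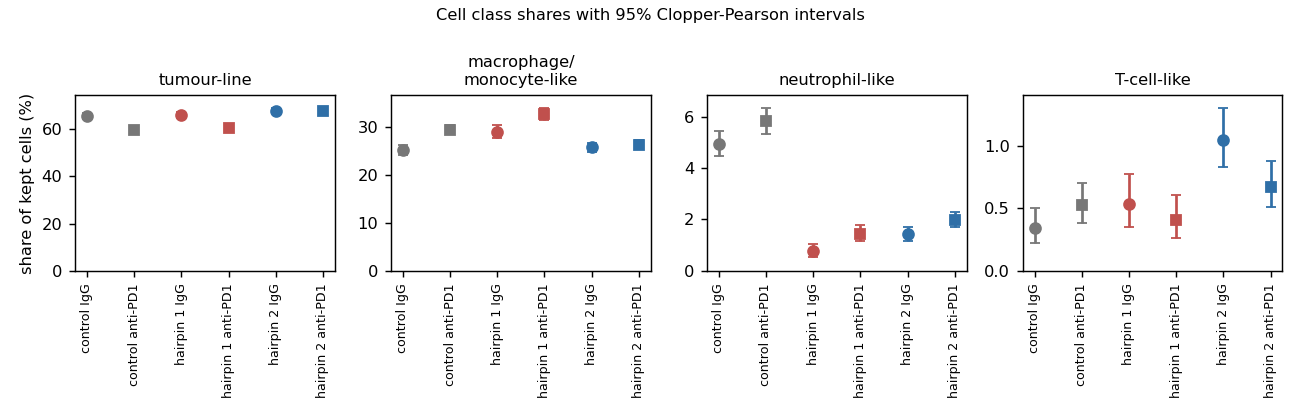
Shares of cell classes in each library, with exact 95% Clopper-Pearson intervals that cover counting error only.

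No other class had 50 cells in every library. With at least 20, edgeR called 16 genes for the knockdown in neutrophils (10 higher, 6 lower; DESeq2 2), among them Isg15 (1.35; 353 and 471 CPM in control, 640 to 1351 in knockdown) and Rsad2 (1.65; 508 and 803 CPM, 841 to 3104) higher and Chil3 (-2.51), Arg1 (-1.94) and Mt1 (-1.67) lower. For the knockdown it called 4 genes in dendritic cells (DESeq2 0), 1 in T cells (DESeq2 2) and 0 in endothelial cells (405 at an unadjusted p under 0.05, DESeq2 3). For anti-PD1 it called 6 genes lower in endothelial cells (at least 29 cells per library, DESeq2 12), among them Spp1 (-3.51 ± 0.20; 1385 to 2294 CPM with IgG, 146 to 218 with anti-PD1) and Grem1 (-3.34 ± 0.27), 5 in neutrophils (DESeq2 4) and 1 in dendritic cells (DESeq2 0). Tumour-line cells held 4130 to 6177 CPM of Spp1 and 1804 to 4231 CPM of Grem1.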

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

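The tests on the mix of clusters, on RNA from tumour-line cells, on haemoglobin-rich barcodes, the splits of samples for single genes and the splits within lines were chosen after the result was seen.

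Hairpin 2 and hairpin 1 differed in 4794 genes in tumour-line cells and 1636 in macrophage/monocyte-like cells, by a direct test of the difference between the lines. For the tumour-line genes, unequal depth of the summed counts is argued against as the whole cause, since 93.74% of the calls were left after thinning all libraries to the smallest. The sums ranged only from 48461922 to 72113992 UMIs before thinning. Thinned sums keep differences in depth per cell, which were not tested. Tumour-line cells had a median of 12777 and 9711.5 UMIs in hairpin 1 and 9074 and 9627 in hairpin 2, IgG before anti-PD1. A different mix of clusters as the whole cause is argued against by the lowest median kept within a cluster, 51.43% of the log2 fold change, and whole-chromosome copy differences by 0% of 4782 called genes on a chromosome with a shifted median. Open and untested are off-target effects of the hairpins, subclonal or part-chromosome differences, the strength of the knockdown, and any difference in handling, since each line has its own libraries. No biological explanation was tested.

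Of the genes in macrophage/monocyte-like cells 34 were lower in knockdown tumours. RNA or doublets from neutrophils could supply a median of 1.3% of their level in control libraries, under 20% for 31 of 34, and stay open for S100a8 and S100a9, which set the scale, and for Cxcr2 (28.6%). A different mix of clusters as the whole cause is argued against by the lowest median of 51.97% of the log2 fold change kept in a cluster, in cluster 18. RNA from tumour-line cells, scaled by Xist, is argued against as the whole cause, since it could supply at most 17.49% of the level of any of the 34, reached by Gpnmb. A response of host cells to the knockdown is a hypothesis, and a difference of the control line from both others stays open, since the control has 1 line.

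Haemoglobin genes were higher in macrophage/monocyte-like cells with anti-PD1. In the highest library, control anti-PD1, 1768 of 1903 haemoglobin UMIs came from 1 barcode, and without it the level fell by 92.9%, from 219 to 15.5 raw CPM. A single barcode rich in haemoglobin is a candidate source for that library. Without the richest barcode of each library anti-PD1 stayed above IgG in 3 of 3 lines (15.5 against 8.43, 23.8 against 4.06 and 7.02 against 4.16 raw CPM), and this part stays open. Tumour-line cells, treated alike, had 4.86 against 2.17, 8.61 against 2.54 and 2.20 against 2.08 raw CPM. The difference was therefore not particular to macrophage/monocyte-like cells. No biological explanation was tested.

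For anti-PD1 the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For single genes the real count was 0 in both classes (highest other 1 and 0), so a result of 10 of 10 splits was fixed in advance and says nothing about chance. For gene lists 3 of 10 splits gave as many in tumour-line cells (real count 15, highest other 19) and 7 of 10 in macrophage/monocyte-like cells (real count 10, highest other 21). Of the 10 splits 6 put both libraries of a line on the same side and so hold line differences, and among the 4 others the real count of lists was the highest in both classes (highest other 13 and 8), but 4 splits are too few for a share under 0.05.

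The interaction test on gene lists with a preset correlation found a difference between knockdown and control in the response to anti-PD1 for 13 lists in tumour-line cells, none of them with an estimated correlation (adjusted p between 0.684 and 0.883). Their median interaction log2 fold changes were 0.427 for interferon gamma, 0.385 for type I interferon, 0.0954 for phagocytosis, 0.270 for proinflammatory, 0.163 for G2/M, -0.0783 for sterol synthesis, 0.0786 for glycolysis and hypoxia, -0.160 for mitochondrial respiration, 0.378 for NF-kB and chemokine, 0.104 for heat shock, 0.184 for macrophage marker, 0.385 for neutrophil marker and 0.365 for endothelial marker genes. In macrophage/monocyte-like cells 11 lists did so (adjusted p 0.954 with an estimated correlation), with medians of -0.325 for MHC class II, 0.126 for alternative activation, 0.178 for glycolysis and hypoxia, -0.0767 for mitochondrial respiration, 0.135 for antioxidant, 0.113 for melanocyte differentiation, -0.0960 for ribosomal, -2.91 for haemoglobin and for erythroid marker, 0.377 for neutrophil marker and -1.79 for mast cell marker genes. The haemoglobin value depends on single barcodes: the interaction of the summed haemoglobin CPM was -3.15 with all barcodes and 0.77 without the richest barcode of each library.

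Some shares moved one way with anti-PD1 in the control line and the opposite way in both knockdown lines, or the reverse, a difference that was not tested. The log2 difference in control minus the mean of the knockdown lines was 1.13 for T cells, 0.934 for dendritic cells, 1.43 for mast cells and basophils and -0.738 for the unnamed cells. The unnamed cluster, tested only as an alternative with at least 20 cells per library, held 591 cells, 1.37% of all kept cells, and 1207 cells at resolution 0.5.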

How the results depend on the processing

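Robust dispersions, the other sets of tumour-line clusters, sums of the libraries of a line and shares without each library were chosen after seeing the data. Over 34 results that answer a comparison, 249 of 284 alternatives were marked unchanged, 17 weaker, 17 stronger, 1 moved and 0 reversed. For 16 of these results, the shares, unchanged means a shift under 1 SD of the differences, and direction was not checked. For the others it means the same direction and side of the threshold. Without single libraries, share differences could change sign, as for dendritic cells with the knockdown (-0.326 to 0.608). Over 426 values of single named genes, 5825 of 6160 alternatives kept the direction and the side of the threshold, 163 were weaker, 172 stronger and 0 reversed. A value without a call that stayed without one counts as unchanged, and many of these genes come from fits with 0 calls. Agreement was largely fixed in advance for those genes, so the share of unchanged values does not measure robustness. DESeq2 called 1404 genes for the knockdown in tumour-line and 202 in macrophage/monocyte-like cells, and 665 between hairpins in macrophage/monocyte-like cells. Without the filter on low counts edgeR called 57 for the knockdown in tumour-line cells, and in macrophage/monocyte-like cells 969 for the knockdown, 17 for anti-PD1 and 9 for the interaction. With line as a block it called 1 for anti-PD1 and 1 for the interaction in tumour-line cells, and 8 and 10 in macrophage/monocyte-like cells, and the called lists numbered 20 for the interaction in tumour-line cells and 16 for anti-PD1 in macrophage/monocyte-like cells. With an estimated correlation 0 lists were called by camera in each class for the knockdown, anti-PD1 and the interaction. With at least 20 cells, other classes had 23 genes called for the knockdown (DESeq2 10), 12 for anti-PD1 (DESeq2 16) and 14 for the interaction (DESeq2 0). The macrophage/monocyte-like share difference for anti-PD1 was 0.0039 with immune cells as the denominator. Leaving out each library gave 2528 to 4451 genes between hairpins in tumour-line cells and 1 to 31 for the knockdown in macrophage/monocyte-like cells, where a control left with 1 library is assumed to vary like the others. Robust dispersions called 57 genes for that knockdown, and the libraries of each line summed gave 0. The log2 fold change of Slc39a9 in tumour-line cells was -1.31 to -1.08 without each library. The cause of these changes was not tested. The interaction could not be fitted without either control library. Fibroblasts and mast cells, with 13 and 8 cells in their smallest library, were not tested for genes, and what depth limits in the rare classes was not tested.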

Other observations

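Among neutrophils, tested with at least 20 cells per library, Isg15 (log2 fold change 1.35) and Rsad2 (1.65) were called higher in knockdown tumours. Ifit2 (2.72) was at 31.2 and 36.4 CPM in control, 36.5 and 0 in hairpin 1 and 295 and 452 in hairpin 2, anti-PD1 before IgG, and the hairpin 1 IgG library held 39 neutrophils. Chil3 (-2.51), the arginase gene Arg1 (-1.94) and Mt1 (-1.67) were called lower. These genes were picked after their values were seen, and no set test was run in this class. The test on this class was planned as an alternative. DESeq2 called 2 genes in this class where edgeR called 16.

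The unnamed cluster of 591 cells was led by Ctsk, Acp5, Mmp9, Slc9b2, Atp6v0d2 and Ocstamp, genes known from osteoclasts, and expressed Y-linked genes. No marker list for osteoclasts was fixed, so the cluster was left without a name. It made up 1.64% of control IgG, 1.42% of control anti-PD1, 1.63% of hairpin 1 IgG, 2.69% of hairpin 1 anti-PD1, 0.537% of hairpin 2 IgG and 0.674% of hairpin 2 anti-PD1 cells. At resolution 0.5 the unnamed cluster led by Ctsk, Acp5 and Mmp9 held 1207 cells and 2.29%, 2.23%, 3.93%, 5.82%, 1.76% and 1.85% of these libraries.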
